A study of Mus musculus with 4 samples.

How the data were processed

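The series holds 4 RNA-seq libraries from mouse ventricle at postnatal day 21, 2 from mice that overexpress Cdk8 specifically in the heart (Cdk8Tg) and 2 from wild-type mice (WT), all male and on the C57BL/6 background. Per the labels' protocols, ventricles were flash frozen, total RNA was extracted with Trizol, polyadenylated RNA was enriched and stranded TruSeq libraries were made. Per the submitters' processing notes, reads were aligned with TopHat (version 1.0.0 of the alignment app) to mm10, and Cufflinks and Cuffdiff were used after that. The versions of Cufflinks and Cuffdiff, the annotation and the strand setting are not given in the sources used here. Groups and replicate numbers were taken from the sample titles. The labels do not say outright that each library came from a separate animal, so p-values measure only the spread between these samples, which may be technical.

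The first deposited table holds FPKM per gene and library, as the authors made them, with 23847 rows and 23352 gene symbols. The scaling between libraries is not given in the sources used here, and the columns summed to 448495, 440324, 510844 and 508247 FPKM for Cdk8Tg replicates 1 and 2 and WT replicates 1 and 2. The second deposited table is the authors' Cuffdiff comparison and gives, per the file headers, an FPKM per group with a p-value and a q-value. Of the genes in the authors' deposited table, 12393 were tested, 10803 were set aside as untested, 154 had too little data and 2 too much. Its FPKM per group were 1.27 times (WT) and 1.14 times (Cdk8Tg) the mean of the first table's libraries, as medians over 7476 genes, which shifts its log2 changes by -0.16 against those computed here. Its columns of fold change and test statistic were not used, because some of their cells held spreadsheet errors.

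FPKM are not counts, so limma 3.58.1 in R 4.3.3 was run on log2(FPKM + 1), with a trended empirical Bayes variance and 2 residual degrees of freedom, over all 4 libraries and without covariates. Fold changes on the log2(FPKM + 1) scale understate the change of genes with low FPKM. Rows with a mean FPKM of at least 1 over the 4 libraries were tested, which left 11888. Benjamini-Hochberg adjusted p-values under 0.05 were called. Symbols on several rows (252 symbols, 747 rows) were kept as separate rows, of which 108 were tested and 17 called, and they were left out of the genes named. Group values are mean FPKM ± SD with n = 2, and log2 changes are Cdk8Tg minus WT with the SE from limma.

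Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 38 lists that had at least 5 measured members, and again with an estimated correlation and with fry. The estimated correlation rested on 2 residual degrees of freedom. That version thus had little power, and a lack of calls there cannot tell whether a list changed. Of 43 lists, 5 had too few members for a test, among them a list of mitochondrial genome transcripts with 0 measured members. Camera sets the members of a list against all other tested genes. Its calls of higher or lower are thus relative to these genes, and the median log2 change of all tested genes was 0.13 as deposited. The test, the filter, the lists, the rule for named genes and all alternatives except scaling to an equal FPKM sum were fixed before the data were examined. That rule took Cdk8, then the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, leaving out predicted, non-coding, clone-named and repeated symbols, and then up to 4 members per list by smallest p. Not every gene that the rule selects is printed. Left-out symbols made up 180 of the calls. Other genes are named where a count of 5 or fewer fell outside the rule, or where a feature was singled out, and these were chosen after their values were seen.

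Alternatives were other pseudocounts (0.1 and 5), no filter and a minimum of 5 FPKM, median-of-ratios scaling, quantile normalization, empirical Bayes without a trend and with robust variance, the replicate number as a block, leaving out each library in turn, the authors' calls, and a minimum log2 change of 1. Median-of-ratios factors were 1.04, 1.06, 0.958 and 0.944 in the order given for the sums. When a library is left out, its group has a single sample, which is assumed to vary like the other group.

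No read counts were used. Depth was estimated from the steps between FPKM values under 0.1 in genes with 1 annotated transcript of more than 800 bases, with 320 to 339 such genes per library. This gave 12.1, 11.8, 13.8 and 13.8 M (mega) fragments, a relative depth of 0.876, 0.847, 1 and 1.00, and estimates of low genes rest on few fragments. These figures are depths only if each library's FPKM were scaled by its own fragment total, which the sources used here do not state. Otherwise they reflect the scaling. The procedure was tested on data simulated for this comparison over 11888 genes, 200 of them changed. It recovered 16.4% of changes of 0.5 on the log2 scale, 67.2% of changes of 1 and 97% of changes of 2, and 4.8% of its calls were unchanged genes. In that simulation, changes of 0.5 were thus often missed. The real data held 2958 calls, against 200 changed genes simulated. The adjusted threshold therefore differs, and these rates need not hold here.

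Coordinates and transcripts were taken from GENCODE M21 on GRCm38, the assembly that mm10 names, and 21679 symbols matched it. Shared sequence was measured as the percentage of the 31-base stretches of a gene's longest coding transcript that also occur in annotated transcripts of other genes. Values of Cdk8 (24.4%), Acaca (56.8%), Ldhb (41.4%), Ckb (36.8%), Ldha (34.2%) and Bnip3 (26.6%) are uncertain for this reason, as are others named in the text. Exons of Bax, Pfkm, Tnni3 and Med12 overlap other annotated genes on the same strand. Overlaps with antisense genes remain uncertain, since the strand setting is not known. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.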

Results

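Polyadenylated RNA was sequenced from the ventricles of male C57BL/6 mice at postnatal day 21. Cdk8 was overexpressed specifically in the heart in 2 samples (Cdk8Tg), and 2 samples were wild type (WT). Cdk8 is the cyclin-dependent kinase of Mediator, the complex that links transcription factors to RNA polymerase II. The series addresses the effect of raised Cdk8 on gene expression in the heart. The deposited values were FPKM, fragment numbers scaled to transcript length and sequencing depth, for 23847 rows with 23352 gene symbols. An FPKM of at least 1 was reached by 11892 and 12030 rows in Cdk8Tg replicates 1 and 2, and by 11704 and 11570 rows in WT replicates 1 and 2. The steps between low FPKM values put the depth at about 12.1 and 11.8 M (mega) fragments in the Cdk8Tg libraries and at 13.8 and 13.8 M in the WT libraries. At that depth a 2-kb transcript at 1 FPKM rested on 24.3, 23.5, 27.6 and 27.5 fragments in the same order. These estimates assume FPKM scaled by each library's own fragment total, which the sources used here do not state. A difference in depth between the groups is therefore not established. Across genes, which are not independent replicates, log2 values correlated at 0.980 between the Cdk8Tg libraries, at 0.988 between the WT libraries and at 0.952 to 0.959 between groups.

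Cdk8 itself was 869-fold higher in the Cdk8Tg ventricles. It stood at 7309 and 8122 FPKM in the Cdk8Tg libraries and at 7.89 and 9.86 FPKM in the WT libraries, with means of 7716 ± 575 and 8.87 ± 1.39 (SD, n = 2 per group). The log2 change was 9.62 ± 0.13 (SE; limma, Benjamini-Hochberg adjusted p = 1.8e-05). Cdk8 transcripts made up 1.63% and 1.84% of the FPKM sum in the Cdk8Tg libraries, against 0.0015% and 0.0019% in WT. The gene (ENSMUSG00000029635.15) lies on chromosome 5 at 146231230 to 146302874 of GRCm38.

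The response reached well beyond Cdk8 and went in both directions. Of 11888 genes tested with limma, 2958 changed, of which 2009 rose and 949 fell, and 4950 had an unadjusted p under 0.05. Among these calls, 210 genes rose and 204 fell by at least 1 on the log2 scale. On the deposited scale the groups did not overlap for 70.3% of tested genes, against 33.3% by chance with 2 libraries per group. That chance value assumes no difference in scale between the groups. The median-of-ratios factors were 1.04 and 1.06 in Cdk8Tg and 0.958 and 0.944 in WT, and such a shift raises the share. The balance of rises and falls depended on scaling. As deposited, the median log2 change of all tested genes was 0.13 and 67.9% of the calls were rises. With median-of-ratios scaling, which brought that median to 0.00, 946 genes rose and 1385 fell, so that 40.6% were rises. Quantile normalization gave 992 rises and 1039 falls. Scaling every library to the same FPKM sum, a choice made after the data were seen, gave 4899 rises and 653 falls with a median of 0.30. Under the deposited, the median-of-ratios and the equal-sum scale alike, 946 genes rose and 653 fell. These were all rises of the median-of-ratios scale and all falls of the equal-sum scale. Each of these scales multiplies a library by a factor, which shifts nearly all log2 changes together, so such an overlap had to arise. Quantile normalization shared 962 rises and 836 falls with the deposited scale. Because the balance depended on scaling, counts for the lists below are given on the deposited scale and again after median-of-ratios scaling. The number of calls was 2380 without Cdk8Tg replicate 1, 1304 without Cdk8Tg replicate 2, 628 without WT replicate 1 and 287 without WT replicate 2, with 1 residual degree of freedom in each case.

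Apart from Cdk8, the 12 largest rises included genes of the contractile apparatus that belong to slow skeletal, fetal or smooth muscle. Tnni1, the slow skeletal and fetal troponin I, stood at 240 ± 20.7 FPKM in Cdk8Tg and 1.15 ± 0.512 in WT (SD, n = 2 per group), a log2 change of 6.83 ± 0.17 (SE; limma, Benjamini-Hochberg adjusted p = 2.4e-04). Cnn1, the smooth muscle calponin, rose by 4.65 ± 0.24, Tpm2, beta-tropomyosin, by 3.45 ± 0.13, and Myl9, a regulatory light chain of smooth muscle myosin, by 3.18 ± 0.14. Acta1, skeletal alpha-actin, rose from 162 ± 16.7 to 1403 ± 108 FPKM, and Myh7, the slow beta-myosin heavy chain, from 57.0 ± 7.73 to 379 ± 158 FPKM. In the authors' deposited table Myh7 was at 9.62 FPKM in WT and 357 FPKM in Cdk8Tg. Ppp2r2b, a regulatory subunit of protein phosphatase 2A known mainly from brain, was at 34.6 and 41.9 FPKM in the Cdk8Tg libraries, at 0.073 FPKM in WT replicate 1 and listed at 0 in WT replicate 2, with a log2 change of 5.24 ± 0.13. Sypl2, a synaptophysin-like membrane protein of muscle, rose by 2.95, Bambi, a decoy receptor of TGF-beta signalling, by 2.90 and Pcbd1, a pterin dehydratase, by 2.77. Hspa1a and Hspa1b, the inducible heat shock proteins of the Hsp70 family, rose by 2.48 and 2.45. Of the 31-base stretches of Hspa1b, 67.6% also occur in Hspa1a, so the split between this pair is uncertain. Likewise, 31.7% of those of Myh7 occur in Myh6. On GRCm38, Tnni1 lies on chromosome 1 at 135779434 to 135810989, Ppp2r2b on chromosome 18 at 42637432 to 43059471, and Cnn1 on chromosome 9 at 22099216 to 22109630. The limma adjusted p of these 12 genes lay between 2.4e-04 and 0.0066. The call of Myh7 was lost without WT replicate 2 (log2 change 2.52, limma Benjamini-Hochberg adjusted p = 0.054).

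The 12 largest falls included genes whose expression is typical of mature striated muscle. Rpl3l, the muscle-specific paralog of ribosomal protein L3, dropped from 143 ± 10.9 FPKM in WT to 13.2 ± 2.29 in Cdk8Tg (SD, n = 2 per group), a log2 change of -3.35 ± 0.13 (SE; limma, Benjamini-Hochberg adjusted p = 8.7e-04). Art1, a muscle ADP-ribosyltransferase, changed by -3.35 ± 0.26, and its exons overlap those of Chrna10 on the opposite strand. Ces1d, a carboxylesterase that hydrolyses lipid esters, changed by -3.33 ± 0.57, and the water channel gene Aqp4 by -3.01 ± 0.12, from 11.9 ± 0.957 to 0.604 ± 0.118 FPKM. Fbp2, the muscle fructose-bisphosphatase, changed by -2.66 ± 0.16, and Casq1, the skeletal calsequestrin that buffers calcium in the sarcoplasmic reticulum, by -2.60 ± 0.32. The remaining falls were Trabd2b at -2.82, Phyhd1 at -2.78, Csdc2 at -2.63, Lrrc15 at -2.50, Rhobtb1 at -2.49 and Lrg1, a secreted glycoprotein, at -2.48. Exons of Phyhd1 overlap another annotated gene on the same strand, so its value is uncertain. On GRCm38, Rpl3l lies on chromosome 17 at 24727820 to 24736143, Art1 on chromosome 7 at 102101743 to 102113933, and Aqp4 on chromosome 18 at 15389496 to 15410982. The call of Ces1d was lost without WT replicate 2 (log2 change -2.76, limma Benjamini-Hochberg adjusted p = 0.091), with no filter on low values (adjusted p = 0.069) and with robust variance (adjusted p = 0.089).

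**Figure D1:**
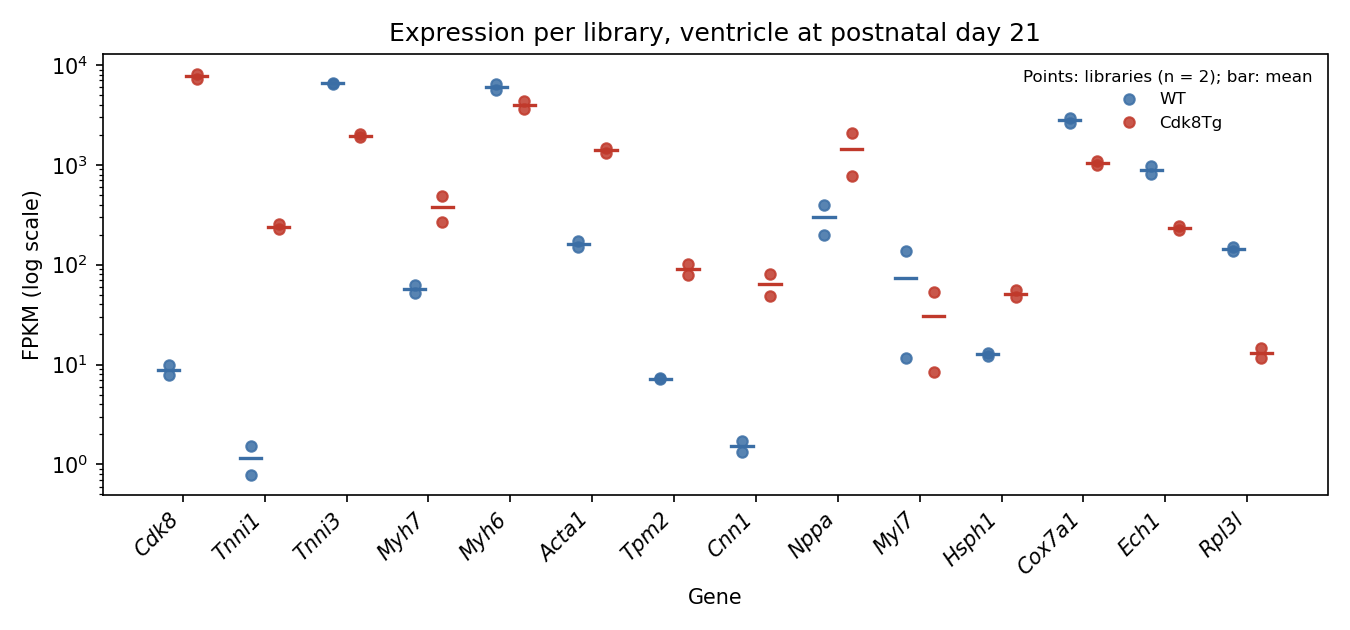
FPKM on a log axis of 14 genes in ventricle, with 2 WT libraries in blue and 2 Cdk8Tg libraries in red; points are libraries and bars are group means. Cdk8 and Tnni1 differed by 869-fold and 209-fold in the means, whereas the atrial light chain gene Myl7 ranged from 8.51 to 136 FPKM with overlapping groups.

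Cardiac stress genes were higher in the Cdk8Tg ventricles and more adult sarcomere genes fell than rose, while fetal, slow or skeletal isoforms went both ways. Of the 21 cardiac stress genes, 9 rose and 0 fell, against 12 and 0 adjusted over the list alone and 8 and 0 after median-of-ratios scaling. The list's median log2 change was 0.90 and camera called it higher (adjusted p = 7.5e-04, and adjusted p = 0.62 with an estimated correlation). Besides Acta1 and Myh7, Rcan1, a calcineurin target, rose by 1.54 and Nmrk2, a nicotinamide riboside kinase, by 1.47. The natriuretic peptide genes Nppa and Nppb and the stress-responsive gene Ankrd1, named after their values were seen, rose by 2.18, 1.46 and 2.22. Nppa, which atrial muscle also expresses strongly, stood at 780 and 2072 FPKM in Cdk8Tg and at 395 and 199 FPKM in WT. The atrial light chain gene Myl7 was at 8.51, 52.7, 136 and 11.6 FPKM in the same order, and Myl4 at 72.5, 281, 94.3 and 11.7. Among the 18 measured fetal, slow or skeletal isoforms, 8 rose and 4 fell, with the same counts adjusted over the list alone and 7 and 4 after median-of-ratios scaling. The median was 0.64 and camera did not call the list (adjusted p = 0.12, and adjusted p = 0.57 with an estimated correlation), although it did after median-of-ratios scaling (adjusted p = 0.0096), without Cdk8Tg replicate 1 (adjusted p = 0.0093) and without WT replicate 1 (adjusted p = 0.030). Tnni1, Tpm2, Myl9, Acta1, Tnnt1 and Ckb were among the rises. The falls were Tnni2 and Casq1 of fast or skeletal muscle, by 1.99 and 2.60, myoglobin (Mb) and the muscle creatine kinase Ckm. Of 26 adult sarcomere genes, 2 rose and 11 fell, against 2 and 12 both adjusted over the list alone and after median-of-ratios scaling. The median was -0.23 and camera called the list lower (adjusted p = 2.6e-06, and adjusted p = 0.57 with an estimated correlation). Quantile normalization ended that call (adjusted p = 0.69). Tnni3, the adult cardiac troponin I, fell from 6549 ± 87.1 to 1953 ± 88.8 FPKM (SD, n = 2 per group), a log2 change of -1.75 ± 0.11, while Tcap, Myom2 and Myoz2 changed by -1.76, -1.36 and -1.08. The rises were Nebl and Smyd1, by 0.47 and 0.53. Myh6, the adult alpha-myosin heavy chain, changed by -0.59, and by 0.09 with no call under quantile normalization. Of the 23 genes named for these lists, 23 kept their call without Cdk8Tg replicate 1, 21 without Cdk8Tg replicate 2, 14 without WT replicate 1 and 11 without WT replicate 2. Nppa was among those lost without Cdk8Tg replicate 2 (limma Benjamini-Hochberg adjusted p = 0.077). Nppb lost its call after median-of-ratios scaling (limma Benjamini-Hochberg adjusted p = 0.057), with quantile normalization (0.055), without a variance trend (0.051), with robust variance (0.10) and with no filter (0.12). Nppa lost its call with robust variance and with no filter, Mb and Ckm theirs with quantile normalization, and Myh6 its own on the equal-sum scale.

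Structural genes of the cell membrane and cardiac transcription factors went both ways. Of 27 genes of the intercalated disc and costamere, 2 rose and 6 fell, against 7 and 6 adjusted over the list alone and 0 and 7 after median-of-ratios scaling. The falls included Sgca and Sgcb, of the sarcoglycan complex that anchors the membrane, the desmosomal cadherins Dsg2 and Dsc2, and Itgb1bp2, with Sgca at -1.41. The rises were the catenin genes Ctnnb1 and Ctnna1, by 0.47 and 0.36. The list's median was 0.03, its mean -0.05 and its camera direction down, with no call (adjusted p = 0.20, and adjusted p = 0.57 with an estimated correlation). Of 20 cardiac transcription factors and cofactors, 7 rose and 1 fell, against 8 and 1 adjusted over the list alone and 5 and 1 after median-of-ratios scaling. Tbx20 rose by 0.98, Irx4 by 0.93 and Gata4 by 0.79, Ankrd1 is also a member, and Tbx5 changed by -0.45, a call lost on the equal-sum scale. The median was 0.26, with no call by camera (adjusted p = 0.12, and adjusted p = 0.57 with an estimated correlation) except without Cdk8Tg replicate 2 (adjusted p = 0.025). Calls were kept by 10, 9, 5 and 1 of the 12 genes named for this pair of lists without Cdk8Tg replicate 1, Cdk8Tg replicate 2, WT replicate 1 and WT replicate 2.

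Genes of mitochondrial energy metabolism were lower, with most members of each of 3 lists falling. Of 29 genes of fatty acid oxidation, 25 fell and 0 rose, and of 54 nuclear genes of oxidative phosphorylation, 49 fell and 0 rose. Adjusted over the list alone, the falls were 26 and 54, and after median-of-ratios scaling 26 and 52. The median log2 changes were -0.76 and -0.70. Camera called both lists lower (adjusted p = 3.0e-20 and 2.3e-30, and adjusted p = 0.57 for each with an estimated correlation). Ech1, an auxiliary enzyme of beta-oxidation, fell from 893 ± 106 to 233 ± 13.9 FPKM (SD, n = 2 per group), a log2 change of -1.93 ± 0.12. Lipoprotein lipase (Lpl) changed by -1.73, the fatty acid transporter Slc27a1 by -1.32 and the thiolase Acaa2 fell from 563 to 280 FPKM. Cox7a1 and Cox6a2, muscle isoforms of cytochrome c oxidase subunits, changed by -1.42 and -1.25, Ndufs7 of complex I by -0.92 and Sdhc of complex II by -0.80. In the TCA cycle, 12 of 19 genes fell and 0 rose, with 16 falls adjusted over the list alone and 15 after median-of-ratios scaling. Its median was -0.49 (camera adjusted p = 1.4e-11, and adjusted p = 0.57 with an estimated correlation). Idh3b, Sdhb, Idh2 and Idh3g changed by -1.03, -0.94, -0.85 and -0.68. Glycolysis moved in both directions, with 6 rises and 5 falls among 21 genes, 6 and 6 adjusted over the list alone and 5 and 6 after median-of-ratios scaling. The glucose transporter Slc2a1, Pgam1 and Eno1 rose by 0.96, 0.98 and 0.65, and the falls were Pfkm, the muscle phosphofructokinase, at -0.96, Eno3, the muscle enolase, at -1.15, Hk2, Ldha and Ldhb. On the equal-sum scale Hk2, Ldha and Ldhb lost their calls, and with quantile normalization Ldha and Ldhb did. Of the 31-base stretches of Eno1 and Pgam1, 77.2% and 42.1% occur in other annotated genes, so their values are uncertain. The glycolysis median was -0.01, its mean 0.04 and its camera direction down, with no call (adjusted p = 0.40, and adjusted p = 0.84 with an estimated correlation), whereas quantile normalization called it higher (adjusted p = 0.035). All 20 genes named for these lists kept their call without Cdk8Tg replicate 1, and 17, 8 and 3 did so without Cdk8Tg replicate 2, WT replicate 1 and WT replicate 2.

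Several nuclear receptors of metabolism were lower, and genes of hypoxia and lipid synthesis went both ways. Among 23 nuclear receptors and coactivators, 1 rose and 4 fell, with the same counts adjusted over the list alone and 0 and 6 after median-of-ratios scaling. The falls were Rxrg at -1.19, Ppara, the receptor that drives fatty acid oxidation genes, at -0.62, Nr1d2 at -0.47 and Ppard at -0.38, and the rise was Ncoa1 at 0.43. The median was -0.07 and camera called the list lower (adjusted p = 0.015, and adjusted p = 0.57 with an estimated correlation), except without Cdk8Tg replicate 2 (adjusted p = 0.13). Of 18 hypoxia-inducible genes, 2 rose, Slc2a1 and Kdm3a, and 5 fell, Egln3, Hk2, Vegfa, Egln1 and Bnip3, against 3 and 6 adjusted over the list alone and 2 and 6 after median-of-ratios scaling. On the equal-sum scale all 5 of these falls, and those of Nr1d2 and Ppard, lost their calls, and with quantile normalization Vegfa and Bnip3 did. Their median was -0.13 (camera adjusted p = 0.077, and adjusted p = 0.57 with an estimated correlation), and camera called them lower without Cdk8Tg replicate 2 (adjusted p = 0.028) and without WT replicate 1 (adjusted p = 0.040). Of 22 genes of sterol and lipid synthesis, 5 rose and 2 fell, with the same counts adjusted over the list alone and 3 and 2 after median-of-ratios scaling. Insig1, Acaca, Sc4mol, Acly and Cyp51 rose by 0.44 to 0.95, Acacb, the carboxylase isoform of oxidative muscle, changed by -0.74 and Fdft1 by -0.48. That list had a median of 0.22 and no call (camera adjusted p = 0.71, and adjusted p = 0.82 with an estimated correlation). The number of the 19 genes named for these lists that kept their call was 14 without Cdk8Tg replicate 1, 4 without Cdk8Tg replicate 2, 2 without WT replicate 1 and 1 without WT replicate 2.

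Lists of calcium cycling, ion channels and adrenergic signalling were lower by camera relative to all other tested genes. Many of their members had no call, and a few went the other way. Of 25 calcium handling genes, 2 rose and 6 fell, against 3 and 8 adjusted over the list alone and 1 and 9 after median-of-ratios scaling. Casq1 and Hrc, proteins of the sarcoplasmic reticulum, changed by -2.60 and -1.58. The calcium pump gene Atp2a2 changed by -0.97, the release channel gene Ryr2 by -0.81, the channel subunit gene Cacna2d1 by -0.68 and phospholamban (Pln) by -0.57. The rises were the T-type channel gene Cacna1h, by 1.48 ± 0.11 (SE, n = 2 per group), and Camk2d, by 0.36. The median was -0.16 and camera called the list lower (adjusted p = 0.0013, and adjusted p = 0.57 with an estimated correlation), a call that quantile normalization ended (adjusted p = 0.12). Of 25 potassium and sodium channel genes, 10 fell and 0 rose, against 13 and 1 adjusted over the list alone and 13 and 0 after median-of-ratios scaling. Their median was -0.35 (camera adjusted p = 1.7e-06, and adjusted p = 0.57 with an estimated correlation). Kcnd2, a channel of the transient outward current, changed by -2.06, Kcnj3, a muscarinic potassium channel subunit, by -1.64, and Kcnk3, a background potassium channel, by -1.28. Of 23 genes of adrenergic and natriuretic signalling, 1 rose and 5 fell, with the same counts adjusted over the list alone and 0 and 6 after median-of-ratios scaling. The alpha-1A adrenergic receptor gene Adra1a changed by -2.48, Adra1b, Corin, Pde4b and Adcy6 changed by -0.81 to -0.35, and the beta-1 receptor gene Adrb1 rose by 0.50. On the equal-sum scale Adra1b, Pde4b, Adcy6 and Pln lost their calls, and with quantile normalization Ryr2, Pln, Camk2d, Adcy6 and Adrb1 did. The median was -0.06 (camera adjusted p = 0.044, and adjusted p = 0.57 with an estimated correlation). This call was lost after median-of-ratios scaling (adjusted p = 0.066), with quantile normalization (adjusted p = 0.061) and without Cdk8Tg replicate 1 (adjusted p = 0.19). Without Cdk8Tg replicate 1, Cdk8Tg replicate 2, WT replicate 1 and WT replicate 2, calls were kept by 14, 12, 9 and 6 of the 17 genes named for these lists.

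**Figure D2:**
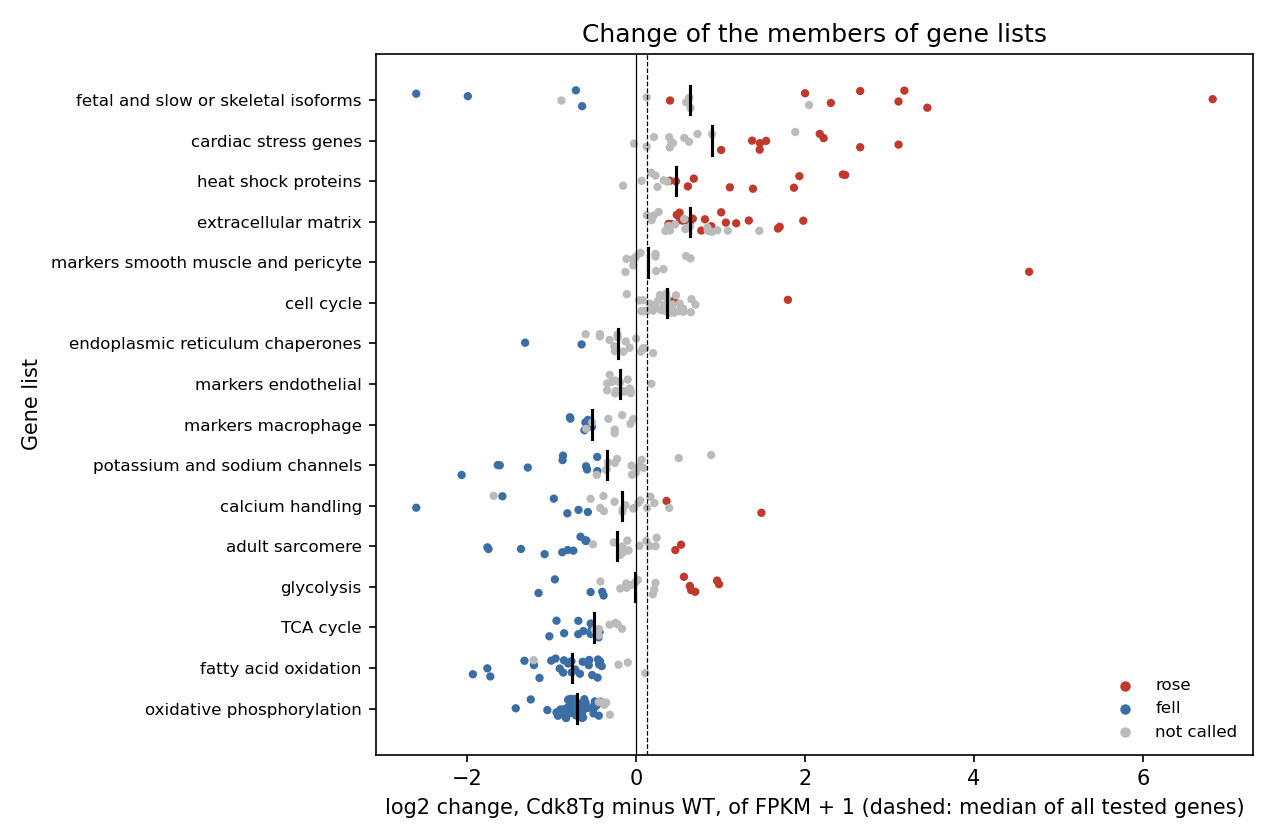
Log2 change of FPKM + 1, Cdk8Tg minus WT, of the measured members of 16 gene lists; each point is a gene, colored by its limma call, black bars are list medians and the dashed line is the median of all tested genes. Medians ran from -0.76 for fatty acid oxidation to 0.90 for cardiac stress genes.

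Extracellular matrix genes were higher, macrophage markers were lower, and markers of most other cell types held few calls. Of 38 matrix genes, 20 rose and 0 fell, against 29 and 0 adjusted over the list alone and 14 and 0 after median-of-ratios scaling. Cilp, a matrix protein of fibroblasts, rose from 2.93 ± 1.58 to 14.1 ± 4.09 FPKM (SD, n = 2 per group), and Col8a1, Loxl1 and Col15a1 rose by 1.68, 0.89 and 0.77. The list's median was 0.64 (camera adjusted p = 1.7e-06, and adjusted p = 0.60 with an estimated correlation). Of 15 fibroblast markers, 7 rose and 0 fell, with the same counts adjusted over the list alone and 3 and 0 after median-of-ratios scaling. Col1a1, Col1a2, Lum and Pdgfra rose by 0.87, 0.82, 0.55 and 0.47. Their median was 0.38 (camera adjusted p = 0.062, and adjusted p = 0.74 with an estimated correlation), and camera called them higher after median-of-ratios scaling (adjusted p = 0.032), without Cdk8Tg replicate 1 (adjusted p = 5.5e-04) and without WT replicate 1 (adjusted p = 0.033). Of 15 macrophage markers, 7 fell and 0 rose, against 8 and 0 adjusted over the list alone and 9 and 0 after median-of-ratios scaling. Cd163, F13a1, Mrc1 and Csf1r changed by -0.78, -0.61, -0.55 and -0.52, and the list's median was -0.52 (camera adjusted p = 1.7e-06, and adjusted p = 0.57 with an estimated correlation). Of 17 endothelial markers, 0 changed by limma either over all genes or adjusted over the list alone, and 1 fell after median-of-ratios scaling, but the list was called lower with a median of -0.19 (camera adjusted p = 0.0012, and adjusted p = 0.57 with an estimated correlation). Of 14 smooth muscle and pericyte markers, Cnn1 was the single rise by every one of these counts, and the list had a median of 0.14 and no call (camera adjusted p = 0.84, and adjusted p = 0.91 with an estimated correlation).

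Among markers of neighbouring tissues, some differed between groups, and others, such as fat genes and the atrial light chain genes, differed between single libraries. Of 10 measured atrial markers, Nppa rose and Kcnj3, Stard10 and Tbx5 fell, with the same calls adjusted over the list alone and after median-of-ratios scaling, and those of Stard10 and Tbx5 lost on the equal-sum scale. The list's median was -0.22 and its mean 0.07, with no call (camera adjusted p = 0.19, and adjusted p = 0.72 with an estimated correlation) except on the equal-sum scale (adjusted p = 0.036). None of the 7 adipocyte markers was called by limma, although their median was 1.05. The brown fat gene Ucp1 was at 10.7 FPKM in Cdk8Tg replicate 2 and listed at 0 in the other libraries, and Pck1 was at 12.6 FPKM there against 0.061, 0.027 and 0.161 FPKM. The camera direction of the adipocyte list was down with no call (adjusted p = 0.82, and adjusted p = 0.94 with an estimated correlation), but up without Cdk8Tg replicate 1 (adjusted p = 0.020) and down without Cdk8Tg replicate 2 (adjusted p = 0.040). The 3 measured skeletal muscle markers, Casq1, Tnni2 and Ckm, all fell and were too few for camera. Of 5 measured valve and cartilage markers, Postn rose by 1.34 (camera adjusted p = 0.33, and adjusted p = 0.81 with an estimated correlation; without WT replicate 1, adjusted p = 0.027). Of 5 Schwann cell and neuron markers, Dbh, the noradrenaline-synthesizing enzyme, changed by -1.36 (camera adjusted p = 0.16, and adjusted p = 0.57 with an estimated correlation). No call was made by limma among 5 erythroid, 6 epicardial, 4 neutrophil or mast cell and 4 Y-linked markers, nor for the 1 lymphocyte marker measured, and these counts were the same adjusted over each list alone and after median-of-ratios scaling. Camera called neither the erythroid list (adjusted p = 0.13, and adjusted p = 0.72 with an estimated correlation) nor the epicardial list (adjusted p = 0.82, and adjusted p = 0.91 with an estimated correlation), although the erythroid list was lower without Cdk8Tg replicate 1 (adjusted p = 0.021) and without WT replicate 1 (adjusted p = 0.0085). Of the 22 genes named for the matrix, cell type and tissue lists, 21 kept their call without Cdk8Tg replicate 1, 16 without Cdk8Tg replicate 2, 9 without WT replicate 1 and 4 without WT replicate 2.

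Heat shock genes were higher, while the list of endoplasmic reticulum chaperones was lower by camera with few called members. Of 17 heat shock genes, 10 rose and 0 fell, with the same counts adjusted over the list alone and 8 and 0 after median-of-ratios scaling. Hsph1, a co-chaperone of the Hsp110 family, rose from 12.7 ± 0.551 to 51.4 ± 6.10 FPKM (SD, n = 2 per group), Hspa4l by 1.38, and Hspa1a and Hspa1b by 2.48 and 2.45. The median was 0.47 (camera adjusted p = 2.8e-04, and adjusted p = 0.57 with an estimated correlation). Of 18 genes on that list, 0 rose and 2 fell, the degradation factor Herpud1 by 1.31 and the chaperone Hspa5 by 0.64. There was 1 fall adjusted over the list alone and 4 after median-of-ratios scaling. Hspa5 stood at 277 and 197 FPKM in the WT libraries and lost its call on the equal-sum scale. Their median was -0.22 (camera adjusted p = 0.0013, and adjusted p = 0.62 with an estimated correlation). Of 20 p53 targets, 8 rose and 2 fell, against 10 and 2 adjusted over the list alone and 4 and 3 after median-of-ratios scaling. Phlda3 rose from 6.77 ± 0.912 to 34.9 ± 0.0782 FPKM, Mdm2 and Bax each rose by 0.51, and the falls were Sesn1 and Perp, at -1.08 and -0.74. The median was 0.41, with no call (camera adjusted p = 0.25, and adjusted p = 0.58 with an estimated correlation). Of 21 genes of the integrated stress response, 5 rose and 2 fell, with the same counts adjusted over the list alone and 4 and 3 after median-of-ratios scaling. The rises were Mthfd2, Aldh18a1, Sesn2, Ddit3 and Atf5, by 0.57 to 1.02, and the falls were Chac1, a glutathione-degrading enzyme, at -2.25 and Cebpb at -1.28. The median was 0.26, with no call (camera adjusted p = 0.75, and adjusted p = 0.94 with an estimated correlation). Among 20 genes of muscle atrophy and autophagy, Becn1 and Atg7 rose and Map1lc3a fell, against 0 rises and 1 fall both adjusted over the list alone and after median-of-ratios scaling. That list had a median of 0.14 and no call (camera adjusted p = 0.85, and adjusted p = 0.94 with an estimated correlation). Calls among the 21 genes named for these lists numbered 17 without Cdk8Tg replicate 1, 12 without Cdk8Tg replicate 2, 9 without WT replicate 1 and 7 without WT replicate 2.

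Cell cycle genes shifted slightly upward as a list, with a single large change. Of 35 measured cell cycle genes, 2 rose and 0 fell, against 1 and 0 both adjusted over the list alone and after median-of-ratios scaling. Ccnd2, cyclin D2, rose from 22.7 ± 4.71 to 80.8 ± 4.74 FPKM (SD, n = 2 per group), and the replication helicase gene Mcm6 rose by 0.45. The median was 0.36 and camera called the list higher (adjusted p = 0.037, and adjusted p = 0.81 with an estimated correlation). The call was lost without Cdk8Tg replicate 2 (adjusted p = 0.18), without WT replicate 2 (adjusted p = 0.56), with a stricter minimum of 5 FPKM (adjusted p = 0.19) and on the equal-sum scale (adjusted p = 0.16). Of 29 interferon response genes, 8 rose and 1 fell, against 10 and 1 adjusted over the list alone and 4 and 1 after median-of-ratios scaling. Ifit2, Ifit1 and Irf7 rose by 1.07, 0.78 and 0.54, and the fall was Iigp1 at -0.72. The interferon median was 0.22 (camera adjusted p = 0.078, and adjusted p = 0.60 with an estimated correlation), and the list was called without Cdk8Tg replicate 1 (adjusted p = 0.047) and with no filter on low values (adjusted p = 0.026). Of 19 TGF-beta targets and ligands, 6 rose and 0 fell, with the same counts adjusted over the list alone and 4 and 0 after median-of-ratios scaling. Bambi, Postn, Tgfb2 and Tgfb3 rose by 2.90, 1.34, 1.30 and 1.11. The median was 0.19 (camera adjusted p = 0.13, and adjusted p = 0.81 with an estimated correlation), with a call without Cdk8Tg replicate 1 (adjusted p = 0.0023). Of 13 Wnt and beta-catenin targets, Fzd2 was the single rise, by 1.32, in all of these counts. Their median was 0.41 (camera adjusted p = 0.13, and adjusted p = 0.72 with an estimated correlation), with calls after median-of-ratios scaling (adjusted p = 0.031), without Cdk8Tg replicate 1 (adjusted p = 0.033) and without WT replicate 1 (adjusted p = 0.027). Of 20 immediate early genes, Zfp36 and Dusp1 fell, by 0.55 and 0.46, and 0 rose, with the same counts adjusted over the list alone and 3 falls after median-of-ratios scaling. The median was -0.01 (camera adjusted p = 0.081, and adjusted p = 0.57 with an estimated correlation), and the list was called lower without Cdk8Tg replicate 2 (adjusted p = 0.028) and without WT replicate 1 (adjusted p = 0.048). Of 13 genes named for these lists, 10 kept their call without either Cdk8Tg replicate in turn, 4 without WT replicate 1 and 3 without WT replicate 2.

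Mediator genes other than Cdk8 showed modest differences. In the kinase module of 7 genes, Cdk8 and its partner Ccnc, cyclin C, rose, the latter by 0.52, with 2 rises and 1 fall adjusted over the list alone and 1 and 1 after median-of-ratios scaling. Cdk19, the paralog of Cdk8, stood at 6.31 ± 0.0445 FPKM in Cdk8Tg and 6.60 ± 0.873 in WT (SD, n = 2 per group; limma, Benjamini-Hochberg adjusted p = 0.75). Med12 was at 5.27 ± 0.301 and 6.99 ± 0.363 FPKM (limma, Benjamini-Hochberg adjusted p = 0.053, and 0.029 after median-of-ratios scaling). The module's median was -0.00, its mean 1.40 and its camera direction up, with no call (adjusted p = 0.75, and adjusted p = 0.82 with an estimated correlation). Of 26 genes of the core complex, 7 rose and 1 fell, with the same counts adjusted over the list alone and 3 and 1 after median-of-ratios scaling. Med10, Med7 and Med21 rose by 1.02, 0.77 and 0.59, and the fall was Med26 at -0.52. The median was 0.20 (camera adjusted p = 0.25, and adjusted p = 0.58 with an estimated correlation). Of the 5 called genes named here besides Cdk8, 3 kept their call without either Cdk8Tg replicate in turn, and 1 without either WT replicate in turn. Over all 38 lists tested, camera called 4 higher and 11 lower. With an estimated correlation it called 0, but that version rested on 2 residual degrees of freedom and had little power. Even oxidative phosphorylation, with 49 of 54 members falling, had a camera adjusted p of 0.57 there. By fry the Mediator kinase module alone was called (adjusted p = 0.012), a list that holds the overexpressed Cdk8 itself.

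The authors' own test gave fewer calls and more falls than rises. Its FPKM were on a scale that shifts log2 changes by -0.16 against those computed here, which favours falls. In the authors' deposited table, 1730 of 12393 tested genes were significant at their false discovery rate, 685 higher and 1045 lower in Cdk8Tg. Among the genes tested here, the authors' deposited table held 1665 such genes, 648 higher and 1017 lower. Of these, 588 of the higher genes also rose and 820 of the lower genes also fell by limma. After median-of-ratios scaling the shared numbers were 528 and 914. The authors' deposited table called 257 genes that limma did not, and limma called 1550 that the table did not. Genes that the authors left untested were not set aside from the latter number. Cdk8 had q = 8.6e-04 in the authors' deposited table, the value held by all 717 genes at its smallest p. Ppp2r2b and Sypl2, by contrast, had q = 0.53 and q = 0.16 in the authors' deposited table, with group values for Ppp2r2b of 0.046 FPKM in WT and 23.5 FPKM in Cdk8Tg.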

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

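The tests of skeletal muscle content, of scaling and of other splits were chosen after the results were seen. Cdk8, the 12 largest rises and the 12 largest falls kept their direction under every alternative that tested them, and at a minimum of 5 FPKM Sypl2 and Lrrc15 were not tested. The log2 change of Cdk8 ranged from 9.12 to 9.80. Over all alternatives, 516 of the list tests kept direction and side of the threshold, 30 gained a call, 40 lost it and 16 turned. For named genes 1878 values stayed the same, 4 gained a call, 435 lost it and 3 turned, mostly where a library was left out or no filter was used. Of 166 called genes named in the text, 89 kept their call with no filter, 150 with median-of-ratios scaling, 141 with quantile normalization, 149 on the equal-sum scale, 154 without a trend, 161 with robust variance and 156 with the replicate block. Without Cdk8Tg replicate 1, Cdk8Tg replicate 2, WT replicate 1 and WT replicate 2 the numbers were 147, 118, 76 and 50. Leaving out a library leaves 1 residual degree of freedom, so that fewer samples account for part of the loss. The pseudocounts, the absence of a trend and robust variance left all counts within 1.5 times.

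The number of changed genes fell to 1055 with no filter on low values (641 rose, 414 fell), where 17947 genes were tested. It was 414 with a log2 change of at least 1 (210 rose, 204 fell) and 1665 by the authors' Cuffdiff calls, with 648 higher. Rises numbered 946 with median-of-ratios scaling, 992 with quantile normalization and 4899 of 5552 calls on the equal-sum scale, an alternative added after the data were seen. Leave-one-out counts ran from 287 to 2380 genes changed, 145 to 1531 rises and 142 to 849 falls. The deviations of same-numbered libraries correlated at -0.026 over genes, so no shared pattern was seen. The labels do not say whether same-numbered samples shared a litter, batch or day. With the number as a block, 2825 genes changed (1855 rose, 970 fell). The block also added camera calls for fetal, slow or skeletal isoforms (higher), hypoxia-inducible genes (lower) and fibroblast markers (higher), for 6 lists higher and 12 lower. Under the block 10 of 166 called genes named in the text lost their call, Mb, Myh6, Ctnna1, Ldha, Ldhb, Cyp51, Acly, Pln, Adcy6 and Atg7.

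Camera with an estimated correlation had little power at 2 residual degrees of freedom. With an estimated correlation, adjusted p was 0.620 for cardiac stress genes, 0.572 for the adult sarcomere, fatty acid oxidation, oxidative phosphorylation and calcium handling, 0.600 for extracellular matrix and 0.811 for the cell cycle. By fry it was 0.177, 0.0535, 0.0535, 0.104, 0.186, 0.174 and 0.351 in the same order. Quantile normalization gave 0.693 for the adult sarcomere and 0.116 for calcium handling and 0.061 for adrenergic and natriuretic signalling, and the cause was not tested. Cell cycle genes had adjusted p = 0.193 at a minimum of 5 FPKM and 0.160 on the equal-sum scale, and leave-one-out values from 2.21e-05 to 0.557.

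These results turned direction, none of them with a call both before and after, and the cause was not tested. Camera adjusted p for epicardial markers was 0.756 with no filter and 0.823 on the equal-sum scale, and leave-one-out values ran from 0.178 to 0.869, turning without WT replicate 2 (0.609). For the integrated stress response it was 0.960 at a minimum of 5 FPKM, 0.778 on the equal-sum scale and 0.139 to 0.791 by leave-one-out, turning without Cdk8Tg replicate 2 (0.667). For muscle atrophy and autophagy it was 0.903 with median-of-ratios scaling and 0.284 to 0.931 by leave-one-out, turning without WT replicate 1 (0.376). Adipocyte markers had 0.785 with median-of-ratios scaling, 0.483 with quantile normalization, 0.812 by fry and 0.0200 to 0.856 by leave-one-out, turning at the lowest, without Cdk8Tg replicate 1. Glycolysis had 0.0350 with quantile normalization and 0.524 by fry. Leave-one-out values ran from 0.152 to 0.849 for smooth muscle and pericyte markers, turning without Cdk8Tg replicate 2 (0.716), and from 0.0272 to 0.959 for valve and cartilage markers, turning at the highest, without WT replicate 2. The log2 change of Myh6 was 0.0866 with quantile normalization. That of Cdk19 was 0.12 on the equal-sum scale and ran from -0.169 to 0.0654 with a library left out.

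Depth limits the low end. At an estimated 12.1, 11.8, 13.8 and 13.8 M (mega) fragments, genes near 1 FPKM rest on few fragments. In the simulation with 2 libraries per group and 200 changed genes, changes of 0.5 on the log2 scale were recovered in 16.4% of cases. That rate need not hold for the real data, where more genes were called.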

Other observations

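The tests of scaling, of skeletal muscle content and of other splits were chosen after the results were seen, and the others before their values were computed. Genes of replication-dependent histones, which package newly copied DNA and whose transcripts mostly lack a poly(A) tail, had higher values in Cdk8Tg. Polyadenylated RNA was enriched here, so these values need not follow the level of all such transcripts. Whether that enrichment differed between the libraries was not tested. This group was chosen after its values were seen. Of 30 such genes, 21 rose and 0 fell, and the median log2 change was 1.04. After median-of-ratios scaling the median was 0.94, with 20 rises and 0 falls. Histone genes share sequence with each other, so single members are uncertain.

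Several muscle-specific isoforms fell while most of their more widely expressed partners did not. Of 13 muscle forms, 11 fell and 0 rose, with a median of -0.89, and these falls prompted the test of the partners. Phkg1, the muscle phosphorylase kinase subunit, changed by -2.46 and Eef1a2, the elongation factor of mature muscle, by -0.63. Among the 13 partners, 3 rose, Eef1a1 from 827 to 1898 FPKM, Phkg2 by 0.57 and Rpl3 by 0.53, and 2 fell, Cox7a2 by 0.53 and Pygb by 1.23. The pair of Pygb went against the pattern, since its muscle form Pygm changed by -0.34 with no call. The partners' median of 0.25 lay at the 98.9 percentile of 10000 random lists matched on expression. The central 95% of these lists spanned -0.36 to 0.20, so the condition set beforehand for a shift between isoforms was met. It shows only that the partners' median lay above that of most lists of genes of like abundance. As single genes, 3 of 13 partners rose, against 2009 of all 11888 tested genes. After median-of-ratios scaling the partners' median was 0.10, with 1 rise and 2 falls. That scaling also lowered the median of the muscle forms, to -1.04. No random lists were drawn on that scale, so the percentile there is not known. With quantile normalization Eef1a2, Phkg2 and Cox7a2 lost their calls. The value of Eef1a1 had been seen before this test, and 71.4% of its 31-base stretches and 87.6% of those of Rpl3 occur in other annotated genes. Calls of these 7 genes were kept by 7 without Cdk8Tg replicate 1, 4 without Cdk8Tg replicate 2, 3 without WT replicate 1 and 2 without WT replicate 2.

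More genes rose than fell in the deposited FPKM. With median-of-ratios scaling 40.6% of calls were rises, but that scaling centres the median change near 0, so the lower share follows from it and leaves open whether scaling was the cause. Loss of share by the 50 most abundant transcripts may contribute, but the test could not tell. Those transcripts held an estimated 21.8% and 20.3% of fragments in Cdk8Tg and 25.6% and 25.2% in WT, and after rescaling to the remainder the median log2 change of 11032 other genes was 0.0587, against 0.128 as deposited. Whether Cdk8 raises or lowers more transcripts in absolute terms cannot be read from these values.

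Ppp2r2b rose from near 0, which could come from an inserted transgene acting on its surroundings, from Cdk8 fragments assigned to it, or from Cdk8 itself. Within 1 Mb, 2 of 7 tested neighbours rose, Prelid2 by 0.95 and Dpysl3 by 1.47, while Sh3rf2 changed by -1.40, a result that could not tell. All 3 of these calls were kept without Cdk8Tg replicate 1, without Cdk8Tg replicate 2 and without WT replicate 1, and 1 without WT replicate 2. Annotated Cdk8 and Ppp2r2b transcripts shared 0 stretches of 31 bases. The sequence of the transgene is not given in the sources used here and was not searched, so misassigned fragments stay open. An effect of Cdk8 was not tested apart from that of the insertion.

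The rise of Cnn1, Myl9, Tpm2 and Tnni1 could reflect more smooth muscle cells or admixed skeletal muscle rather than a change within cardiomyocytes. The median log2 change of 7 other smooth muscle genes was 0.24, with a range of -0.11 to 0.65, which speaks against more smooth muscle as the cause. The 3 measured skeletal muscle markers had a median of -1.99, from -2.60 to -0.64. These falls had been seen before the test was chosen, and WT ventricle also held these transcripts, with Ckm at 1823 FPKM. The falls alone therefore cannot decide on admixed skeletal muscle. Of the 15 markers listed, however, only 3 were measured at a mean FPKM of at least 1. In Cdk8Tg, Casq1 stood at 8.10 FPKM and Tnni2 at 1.16 FPKM, against 240 FPKM for Tnni1. These low levels argue against skeletal muscle that carries the listed markers as the source of the Tnni1 rise. Skeletal muscle without these markers is not covered. A change within cardiomyocytes remains possible but was not tested.

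The grouping of the 4 libraries could not be tested by other splits with any power. The real split gave 2958 genes and the highest other split 1, so that 1 of 3 splits, the real split itself, gave as many, and with 3 splits no share under 0.05 can arise.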
